A study of Homo sapiens with 10 samples.

How the data were processed

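RNA was measured in 10 subcutaneous tumours of HPAF-II, an established human pancreatic adenocarcinoma cell line with a mutation of RNF43, grown in the flank of mice. Per the labels, 5 samples came from mice given ETC-159, an inhibitor of PORCN, the acyltransferase that Wnt ligands need for secretion, and 5 came from vehicle-treated mice. The labels give 56 h for the ETC-159 samples and 0 h for the vehicle samples, whereas the design text of the series speaks of 24 h and 48 h, so the time behind the comparison rests on the sample labels alone. Per the labels' protocols, total RNA was extracted with a Qiagen column kit and made into stranded Illumina libraries after depletion of ribosomal RNA. Polyadenylation was therefore not selected for, and abundant non-coding RNAs are part of the totals.

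The authors deposited 1 gene table per sample in the layout of RSEM, with an expected count and a TPM per gene. The submitters' processing notes list cutadapt, STAR and RSEM and the human build hg38. Their versions, the annotation release, the strand setting and the treatment of reads from mouse cells are not given in the sources used here. Expected counts are the authors' estimates, in which reads that match several genes are shared out, so they need not be whole. Values of paralogs, processed pseudogenes, and histone genes that resemble each other carry that extra uncertainty, and overlapping or antisense genes cannot be held apart with certainty while the strand setting is unknown. The deposited TPM values were used only for alternatives, because TPM keeps no depth.

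The tables held 60433 gene identifiers. Symbols, biotypes and hg38 positions were taken from GENCODE release 44 by identifier without its version suffix, which paired 56321 identifiers (93.2%) carrying 99.75% of the counts. Identifiers without a symbol stayed in the tests. Of 935 memberships in 31 gene lists, 931 were matched to an identifier. Among the members not matched were RPL40, DDX58 and MYLPF. The values of 1 gene that the naming rule selects are not reported here, and it was left out of the search for outlying libraries.

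Expected counts were rounded to whole numbers. Genes were kept by the edgeR function filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14560 genes, and libraries were scaled by TMM. The quasi-likelihood test of edgeR 4.0.16, with robust estimation and group as the only term, was run in R 4.3.3 over all 10 libraries. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Fold changes are ETC-159 over vehicle on the log2 scale, and the standard error (SE) is the absolute log2 fold change without shrinkage divided by the square root of the F statistic. CPM values refer to the TMM-scaled library, and log2 CPM for principal components used a prior count of 2.

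Gene lists were tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01, for the 28 lists with at least 5 tested members. Their p-values were adjusted over these 28 lists. An estimated correlation and fry were alternatives. Counts of list members past the threshold are given after adjustment over all genes tested and adjusted over the list alone. Shares of counts per library, library totals and the number of detected genes (at least 10 counts) were compared by a two-sided exact permutation test over the 252 assignments of 10 libraries. The smallest p this test can give is 0.00794, and its p-values were adjusted over 14 measures.

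The groups, the gene lists, the main test, most alternatives and the rule for named genes were fixed before the data were examined. The rule names a set of genes of Wnt signalling, growth and differentiation, the 10 protein-coding genes with the largest changes in each direction among those past the threshold whose groups did not overlap and whose higher group reached 5 CPM, and up to 4 members with the smallest p in each list plus 1 in the opposite direction. Genes under 5 CPM in both groups are named only within the first part and among host cell markers. The rule does not cover the abundant RNAs RN7SL1 and RN7SL2, host cell markers, or members of families chosen after the results were seen. Any other gene named outside the rule is marked as chosen after its values were seen.

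Total expected counts ran from 8539767 to 11548411 per vehicle library and from 11137100 to 15372113 per ETC-159 library. The test was tested on simulated data drawn from the means and library sizes of these samples, with 14560 genes of which 200 were changed. It recovered 74.6% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 97.0% of those changed 4-fold. Of the calls, 5.53% (10 genes) were false, and 0 genes were called when none was changed. Intervals of the SE covered the true change in 94% of the 200 changed genes. Genes were drawn independently and few were changed, so the simulation does not test the scaling where many genes change together. With few genes changed, the adjusted p threshold also asks for a smaller p before adjustment. The recovery rates therefore need not hold for the real data.

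Alternatives were other scalings (DESeq2 1.42.0 size factors, upper quartile, library size only), other filters on low counts, the DESeq2 Wald test, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, 1 surrogate variable (sva 3.50.0), protein-coding genes only, removal of the host cell lists, each library left out in turn, an adjusted p threshold of 0.01 and a test against a fold of 1.5 (glmTreat). Fits on replicate numbers 1 to 3 only, on 4 and 5 only, and on libraries thinned to equal depth were chosen after seeing the data. The fit on 4 and 5 held the fewest libraries of all fits, so a call can be lost in it for lack of samples alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.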

Results

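HPAF-II xenografts were profiled by total RNA sequencing to follow the transcriptional response to inhibition of PORCN in RNF43-mutant pancreatic cancer. RNF43 is a ubiquitin ligase that removes Wnt receptors from the cell surface. There were 5 ETC-159 samples, labelled 56 h, and 5 vehicle samples, labelled 0 h. By these labels treatment and time differ together, so an effect of ETC-159 cannot be told apart from one of time. Changes after ETC-159 are differences between these 2 groups of samples. The labels do not say outright that each sample came from a separate mouse, so the p-values measure the spread between these samples.

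Libraries of the ETC-159 group were deeper, with 13.13 ± 1.71 M expected counts (SD, n = 5) against 10.07 ± 1.19 M (SD, n = 5) for vehicle (exact permutation p = 0.0159, adjusted p = 0.037). The number of genes with at least 10 counts was 14631 ± 197 (SD, n = 5) after ETC-159 and 14608 ± 187 (SD, n = 5) in vehicle tumours (exact permutation p = 0.849). The 10 most abundant genes of a library, among them the signal recognition particle RNAs RN7SL1 and RN7SL2, took 20.8 ± 1.08% of counts (SD, n = 5) after ETC-159 and 18.6 ± 1.13% (SD, n = 5) in vehicle tumours (exact permutation p = 0.0317, adjusted p = 0.0635). All 20 pairs of libraries within a group differed by more than counting noise, with a chi-square per degree of freedom of 4.50 to 28.3. The biological coefficient of variation was 12.1%. The first principal component held 48.7% of the variance and separated the groups, with vehicle libraries between -39.1 and -22.1 and ETC-159 libraries between 13.3 and 34.9. ETC-159 replicate 2 was the library nearest to vehicle.

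**Figure D1:**
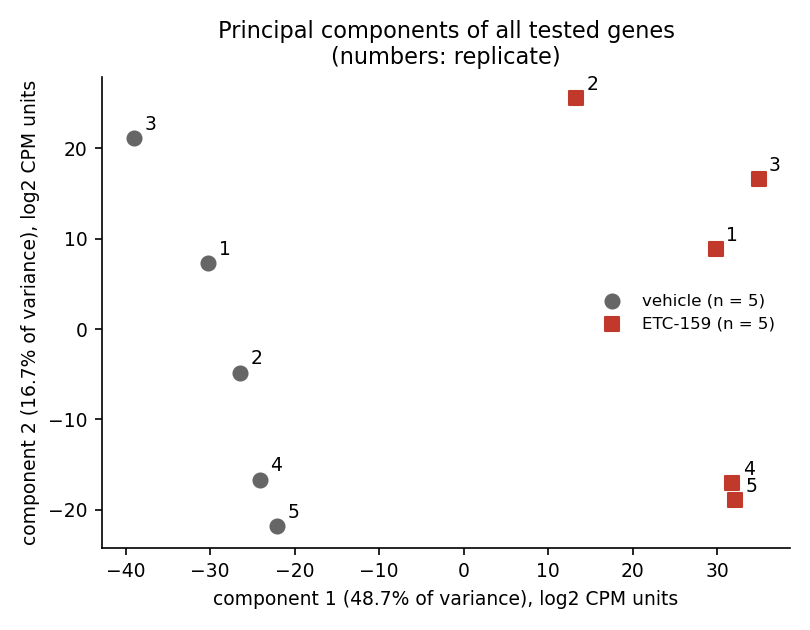
Principal components of log2 CPM over the 14560 tested genes, with 1 point per library, coloured by group and numbered by replicate. The first component (48.7% of the variance) places all vehicle libraries below 0 and all ETC-159 libraries above 0, and on the second (16.7%) replicates 4 and 5 of both groups have the lowest values.

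AXIN2, a scaffold of the beta-catenin destruction complex transcribed in response to Wnt, went from 20.6 ± 1.85 CPM (SD, n = 5) to 3.01 ± 2.61 CPM (SD, n = 5), a 6.63-fold fall. MUC17, a membrane mucin, went from 24.3 ± 8.93 to 396 ± 122 CPM (SD, n = 5 each), and MKI67, a marker of proliferating cells, from 795 ± 124 to 268 ± 67.0 CPM (SD, n = 5 each).

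Across the transcriptome, 5293 of 14560 genes (36.4%) passed the threshold of the edgeR quasi-likelihood test, 2655 higher and 2638 lower after ETC-159. Most changes were small, with a median absolute log2 fold change of 0.45 among the changed genes. At least 2-fold changes were found for 255 genes that rose and 520 that fell. In 3635 genes (24.97%) the groups did not overlap, against 0.794% by chance. Protein-coding genes made up 12443 of the tested genes, with 2510 higher and 2305 lower, and long non-coding RNAs 1175, with 76 higher and 179 lower.

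The balance of directions differed between scalings. With TMM, 50.2% of calls were higher, compared with 41.1% with upper quartile factors, 22.3% with library size only, 11.8% on log2(TPM + 1) and 11.9% on log2(TPM + 0.1). Library size only moved the median log2 fold change of all genes to -0.17 and the medians of all 28 lists down, and on the TPM scales, where the test was limma-trend, it was -0.20 and -0.25, so small changes are relative to the scaling. Rises of small size are thus rises relative to the typical gene.

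Among 30 Wnt target genes fixed beforehand, 21 were tested and 14 fell, none rose, and 15 were lower when adjusted over the list alone. The median log2 fold change was -0.84 (camera adjusted p = 4.1e-10, and adjusted p = 0.0456 with an estimated correlation). AXIN2 (ENSG00000168646, chromosome 17, 65528563 to 65561648) fell by 2.73 ± 0.43 on the log2 scale (SE, edgeR adjusted p = 0.00106). Its values were 2.02, 1.73, 0.60, 7.33 and 3.38 CPM in ETC-159 replicates 1 to 5, and without ETC-159 replicate 4 the log2 fold change was -3.40. SP5, a transcription factor induced by beta-catenin, fell by 2.50 ± 0.24 (SE, edgeR adjusted p = 3.8e-06), and NKD1, an inhibitor of Dishevelled, had a log2 fold change of -2.12 ± 0.20 (SE, edgeR adjusted p = 1.2e-05). LGR5, the R-spondin receptor of intestinal stem cells, went from 2.97 ± 0.43 to 0.591 ± 0.197 CPM, and NOTUM, a secreted deacylase of Wnt ligands, from 2.53 ± 0.66 to 0.598 ± 0.509 CPM (SD, n = 5 each). The log2 fold change of NOTUM was -2.04, and -2.63 without ETC-159 replicate 4. The ubiquitin ligases ZNRF3 and RNF43 fell by 1.31 ± 0.12 and 0.67 ± 0.07 (SE, edgeR adjusted p = 1.8e-06 and 8.3e-06).

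MYC fell by 0.65 ± 0.12 on the log2 scale (SE, edgeR adjusted p = 0.000864) and TCF7 by 0.57 ± 0.11 (SE, edgeR adjusted p = 0.000881). Among replicates 4 and 5 alone, the log2 fold changes were -0.45 for MYC (adjusted p = 0.0921) and -0.44 for TCF7 (adjusted p = 0.0857), each adjusted p the highest of 26 alternatives. CCND1, encoding cyclin D1, was at 284 ± 46.8 and 291 ± 87.2 CPM (SD, n = 5 each) in vehicle and ETC-159 tumours, with a log2 fold change of 0.04 ± 0.20 (SE, edgeR adjusted p = 0.909). LEF1 had at most 2 counts in any library and was not tested.

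**Figure D2:**
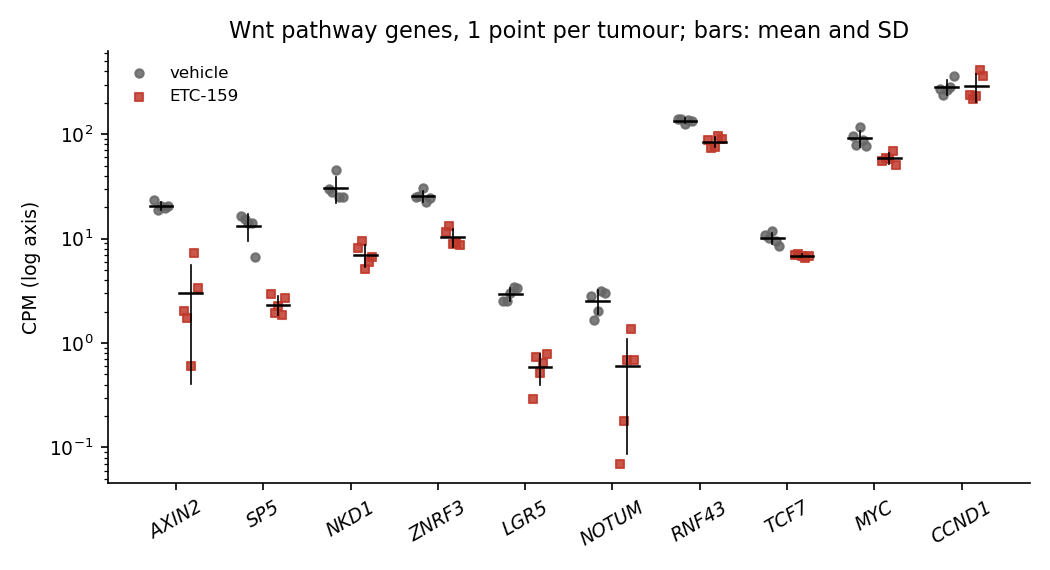
CPM on a log axis of 10 genes of the Wnt pathway, with 1 point per tumour and bars for the mean and SD of each group (n = 5 each). Groups do not overlap for the 9 genes from AXIN2 to MYC, and they overlap for CCND1.

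Ligands, receptors and other machinery of Wnt signalling went both ways, with 9 of 27 tested genes higher and 5 lower, the same counts when adjusted over the list alone (median log2 fold change -0.03, camera direction up, adjusted p = 0.907). The ligand gene WNT7B rose from 29.8 ± 4.36 to 48.1 ± 8.69 CPM and the receptor gene FZD5 from 159 ± 11.3 to 220 ± 14.7 CPM (SD, n = 5 each), with edgeR adjusted p = 0.00109 and 7.3e-05. On log2(TPM + 1) their adjusted p was 0.0593 and 0.102, each the highest of 26 alternatives. FZD6 and the co-receptor gene LRP6 fell by 0.40 ± 0.06 and 0.43 ± 0.07 on the log2 scale (SE, edgeR adjusted p = 8.2e-05 and 0.000413). PORCN, the drug target (chromosome X, 48508959 to 48520814), had 19.9 ± 8.05 CPM in vehicle and 28.1 ± 18.3 CPM in ETC-159 tumours (SD, n = 5 each), with a log2 fold change of 0.50 (edgeR adjusted p = 0.463). It passed the threshold with 1 surrogate variable (adjusted p = 0.0315) and with the replicate number as a block (adjusted p = 0.04955). Its adjusted p ran from 0.000878 to 0.864 over 26 alternatives, the lowest among replicates 4 and 5 alone, a subset chosen partly for its PORCN. PORCN was at 14.0, 14.6, 13.7, 26.1 and 30.9 CPM in vehicle replicates 1 to 5 and at 15.6, 14.8, 14.99, 53.7 and 41.4 CPM in ETC-159 replicates 1 to 5.

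**Figure D3:**
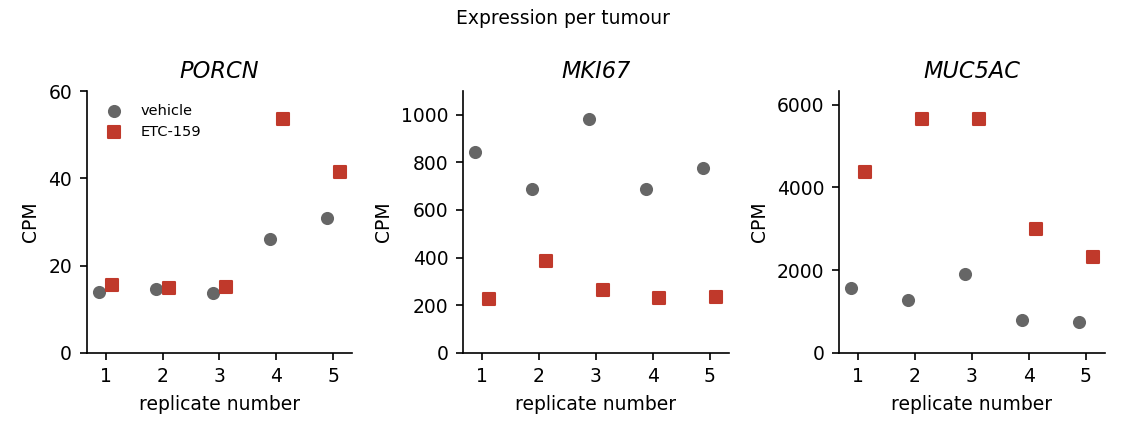
CPM per tumour, by replicate number, of PORCN, MKI67 and MUC5AC. PORCN lies between 13.7 and 53.7 CPM and overlaps between groups, while MKI67 is lower and MUC5AC higher in every ETC-159 tumour than in any vehicle tumour.

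All 52 genes of G2 and mitosis and all 50 genes of DNA replication and G1/S fell, the same counts when adjusted over the list alone. Their median log2 fold changes were -1.48 (camera adjusted p = 5.7e-102, and adjusted p = 0.0398 with an estimated correlation) and -1.06 (camera adjusted p = 3.3e-41, and adjusted p = 0.142 with an estimated correlation). TOP2A, encoding topoisomerase II alpha, went from 230 ± 12.3 to 70.6 ± 11.1 CPM and RRM2, a subunit of ribonucleotide reductase, from 175 ± 10.4 to 50.9 ± 10.7 CPM (SD, n = 5 each; edgeR adjusted p = 2e-08 and 1.7e-07). CCNB1 and MCM2 fell by 1.27 ± 0.10 and 1.11 ± 0.16 on the log2 scale (SE, edgeR adjusted p = 4.6e-07 and 0.000326). ETC-159 replicate 2 had the highest MKI67 of its group, at 384 CPM against 227 to 265 CPM in the other 4 libraries. Without that library, all 52 and all 50 genes were again lower.

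Of 33 genes of homologous recombination and the Fanconi anaemia pathway, 27 fell and 1 rose, the same counts when adjusted over the list alone (median log2 fold change -1.13, camera adjusted p = 1.9e-19, and adjusted p = 0.148 with an estimated correlation). FANCD2 fell by 1.38 ± 0.10, BRIP1 by 1.49 ± 0.12 and RAD51AP1 by 1.46 ± 0.15 on the log2 scale (SE, edgeR adjusted p = 1.2e-07, 4.4e-07 and 3.8e-06). EME1, a subunit of a structure-specific endonuclease, went from 7.94 ± 1.18 to 2.10 ± 1.02 CPM (SD, n = 5 each). The gene that rose was FANCF, with a log2 fold change of 0.25 ± 0.08 (SE, edgeR adjusted p = 0.0237). Its adjusted p was 0.0601 without vehicle replicate 2, 0.0633 without vehicle replicate 4 and 0.0506 without ETC-159 replicate 1, and it ran from 0.0182 to 0.945 over 26 alternatives.

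Among 20 tested inhibitors of cyclin-dependent kinases and other genes of cell cycle exit, 7 rose and 4 fell, and 8 and 4 did so adjusted over the list alone (median log2 fold change 0.12, camera adjusted p = 0.35). The median was -0.03 with library size only and -0.05 on log2(TPM + 1). KLF4, a transcription factor of epithelial differentiation, rose from 29.5 ± 5.87 to 70.1 ± 11.5 CPM (SD, n = 5 each), and CDKN2C, encoding the inhibitor p18, fell by 1.52 ± 0.14 on the log2 scale (SE, edgeR adjusted p = 1.2e-06). CDKN1A, encoding p21, was at 51.5 ± 5.85 and 67.9 ± 16.1 CPM (SD, n = 5 each; edgeR adjusted p = 0.0603). Its adjusted p was 0.0177 by DESeq2 and 0.0137 without ETC-159 replicate 2, and ran from 5.2e-05 to 0.55 over 26 alternatives.

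Of 41 tested genes of secretory and gastrointestinal differentiation, 33 rose and none fell, and 34 rose when adjusted over the list alone. The median log2 fold change was 1.01 (camera adjusted p = 1.8e-29, and adjusted p = 0.092 with an estimated correlation). The gastric mucin MUC5AC went from 1254 ± 499 to 4199 ± 1525 CPM (SD, n = 5 each; edgeR adjusted p = 0.00572), AGR2, a disulfide isomerase of mucin-producing cells, from 1197 ± 105 to 3058 ± 352 CPM and the intestinal keratin KRT20 from 293 ± 44.5 to 1460 ± 240 CPM (SD, n = 5 each; edgeR adjusted p = 8.4e-08 and 8.9e-08). The trefoil factor TFF1 rose from 0.763 ± 0.237 to 12.3 ± 5.78 CPM (SD, n = 5 each), which is 3.97 ± 0.41 on the log2 scale (SE, edgeR adjusted p = 2.5e-05). REG4, a secreted lectin, rose from 79.3 ± 53.3 to 490 ± 228 CPM (SD, n = 5 each; edgeR adjusted p = 0.0101). Among replicates 4 and 5 alone its log2 fold change was 2.95, with adjusted p = 0.145, the highest of 26 alternatives. Its values in replicates 4 and 5 were 48.8 and 18.8 CPM for vehicle and 331 and 187 CPM for ETC-159.

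Among 11 tested genes of stratified and squamous epithelium, 5 rose and 1 fell, the same counts when adjusted over the list alone (median log2 fold change 1.40, camera adjusted p = 1e-05, and adjusted p = 0.188 with an estimated correlation). The median was 0.61 on log2(TPM + 1). By DESeq2, which tested 15 of these genes, it was 0.742. KRT15 rose from 24.5 ± 2.76 to 72.0 ± 10.8 CPM and SPRR3, a cornified envelope precursor, from 2.38 ± 0.49 to 11.9 ± 2.48 CPM (SD, n = 5 each). The gene that fell was TP63, the transcription factor of basal squamous cells, named after its values were seen, with a log2 fold change of -1.24 (edgeR adjusted p = 0.0015). Transcription factors of pancreatic and ductal identity went both ways, with 6 of 17 higher and 5 lower, the same counts when adjusted over the list alone (median log2 fold change -0.23, camera direction up, adjusted p = 0.744). ELF3 rose by 0.83 ± 0.09 and SOX9, a factor of ductal progenitors, fell by 0.78 ± 0.09 on the log2 scale (SE, edgeR adjusted p = 6e-06 and 6.9e-06).

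Ribosomal protein genes fell slightly, with 46 of 78 lower, none higher, and 55 lower when adjusted over the list alone. The median log2 fold change was -0.19 (camera adjusted p = 0.000128, and adjusted p = 0.709 with an estimated correlation). Their share of counts was 1.84 ± 0.0835% in vehicle and 1.46 ± 0.0673% in ETC-159 tumours (SD, n = 5 each; exact permutation p = 0.00794, adjusted p = 0.0222). RPL3 went from 397 ± 42.8 to 309 ± 28.3 CPM and RPS2 from 235 ± 21.4 to 183 ± 14.3 CPM (SD, n = 5 each; edgeR adjusted p = 0.003 and 0.00152). Among replicates 4 and 5 alone, 2 of the 78 genes were lower, the median was -0.10 and the camera adjusted p was 0.212. Many of these genes have processed pseudogenes with near-identical sequence, so the counts of single members are uncertain. Of 79 genes of ribosome biogenesis, 5 were higher and 7 lower, the same counts when adjusted over the list alone (median log2 fold change -0.03, camera adjusted p = 0.744). With library size only 2 were higher and 29 lower. FBL, the rRNA methyltransferase fibrillarin, fell by 0.63 ± 0.10 and TCOF1 by 0.68 ± 0.11 on the log2 scale, and NOP10 rose by 0.42 ± 0.07 (SE, edgeR adjusted p = 0.000229, 0.00036 and 0.000469). On log2(TPM + 1) the adjusted p of NOP10 was 0.159, the highest of 26 alternatives. NOP56 was at 203 ± 25.1 and 175 ± 16.5 CPM and POLR1A, the large subunit of RNA polymerase I, at 108 ± 8.96 and 108 ± 6.68 CPM (SD, n = 5 each; edgeR adjusted p = 0.0626 and 0.962). NOP56 passed the threshold with library size only (adjusted p = 0.00591) and without ETC-159 replicate 2 (adjusted p = 0.0208), and its adjusted p ran from 0.00104 to 0.194 over 26 alternatives.

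Enzymes of nucleotide and polyamine synthesis fell in 16 of 26 cases and rose in none, the same counts when adjusted over the list alone (median log2 fold change -0.27, camera adjusted p = 1e-05, and adjusted p = 0.462 with an estimated correlation). TK1, thymidine kinase, fell by 1.42 ± 0.10 and DTYMK, thymidylate kinase, by 0.84 ± 0.09 on the log2 scale (SE, edgeR adjusted p = 2.1e-07 and 7e-06). Among 33 translation factors 4 rose and 3 fell, the same counts when adjusted over the list alone (median log2 fold change -0.0033, camera adjusted p = 0.928). The sign of this median was positive with DESeq2 size factors. With library size only, 2 of these genes were higher and 19 lower. EIF5 rose by 0.50 ± 0.06 and EEF1G fell by 0.42 ± 0.07 on the log2 scale (SE, edgeR adjusted p = 2.7e-05 and 0.000178), and on log2(TPM + 1) the adjusted p of EIF5 was 0.192, and on log2(TPM + 0.1) it was 0.1924, the highest of 26 alternatives. Of 18 snoRNA host genes, 6 fell and none rose, also when adjusted over the list alone (median log2 fold change -0.20, camera adjusted p = 0.138). On log2(TPM + 1) the camera adjusted p of that list was 0.0415, and on log2(TPM + 0.1) it was 0.0393. With fry, which tests a list against no change and not against other genes, the adjusted p was 0.00991, and with an estimated correlation it was 0.679.

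Sterol synthesis and uptake genes rose in 18 of 25 cases and fell in none, with 21 higher when adjusted over the list alone (median log2 fold change 0.40, camera adjusted p = 5.5e-08, and adjusted p = 0.329 with an estimated correlation). SC5D, a desaturase of the last steps of cholesterol synthesis, rose from 42.9 ± 1.84 to 75.2 ± 3.97 CPM and CYP51A1, the lanosterol demethylase, from 94.1 ± 8.47 to 139 ± 10.8 CPM (SD, n = 5 each; edgeR adjusted p = 1.4e-07 and 4e-05). Genes of axon guidance and related adhesion rose in 11 of 27 cases and fell in 3, the same counts when adjusted over the list alone (median log2 fold change 0.25, camera adjusted p = 0.000158, and adjusted p = 0.188 with an estimated correlation). The plexin PLXNB2 rose from 598 ± 38.1 to 1511 ± 212 CPM and the netrin NTN4 from 55.5 ± 5.36 to 145 ± 17.3 CPM, while the ephrin receptor EPHB3, also a Wnt target of the list above, fell from 222 ± 57.3 to 63.8 ± 16.9 CPM (SD, n = 5 each).

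Genes of the ATF4 and unfolded protein responses rose in 12 of 26 cases and fell in 2, the same counts when adjusted over the list alone (median log2 fold change 0.21, camera adjusted p = 0.0137, and adjusted p = 0.486 with an estimated correlation). On log2(TPM + 1) the median was -0.05, which was 0.144 relative to the median of all genes, with camera adjusted p = 0.00893. HERPUD1 rose by 0.60 ± 0.08 (SE) on the log2 scale and PHGDH, the entry enzyme of serine synthesis, fell from 15.4 ± 3.07 to 6.68 ± 0.99 CPM (SD, n = 5 each; edgeR adjusted p = 2.7e-05 and 1.2e-05). Targets of TGF-beta and BMP fell in 7 of 17 cases and rose in 1, and 8 fell and 2 rose adjusted over the list alone (median log2 fold change -0.16, camera adjusted p = 0.00991, and adjusted p = 0.474 with an estimated correlation). BMP4 and BAMBI, which are also on the Wnt target list, fell by 0.84 ± 0.08 and 1.62 ± 0.15, and ID3 by 2.06 ± 0.22 on the log2 scale (SE, edgeR adjusted p = 3.3e-06, 1.5e-05 and 3.2e-05). BMP2 was the member that rose, with a log2 fold change of 0.63 ± 0.17 (SE, edgeR adjusted p = 0.0145), and with adjusted p = 0.0925 on log2(TPM + 1). Without ETC-159 replicate 2 the camera adjusted p of the TGF-beta and BMP list was 0.0538, and on log2(TPM + 1) it was 0.0954, within a range of 0.000238 to 0.474 over 28 alternatives. With any 1 library left out the median of this list ran from -0.36 to -0.14.

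**Figure D4:**
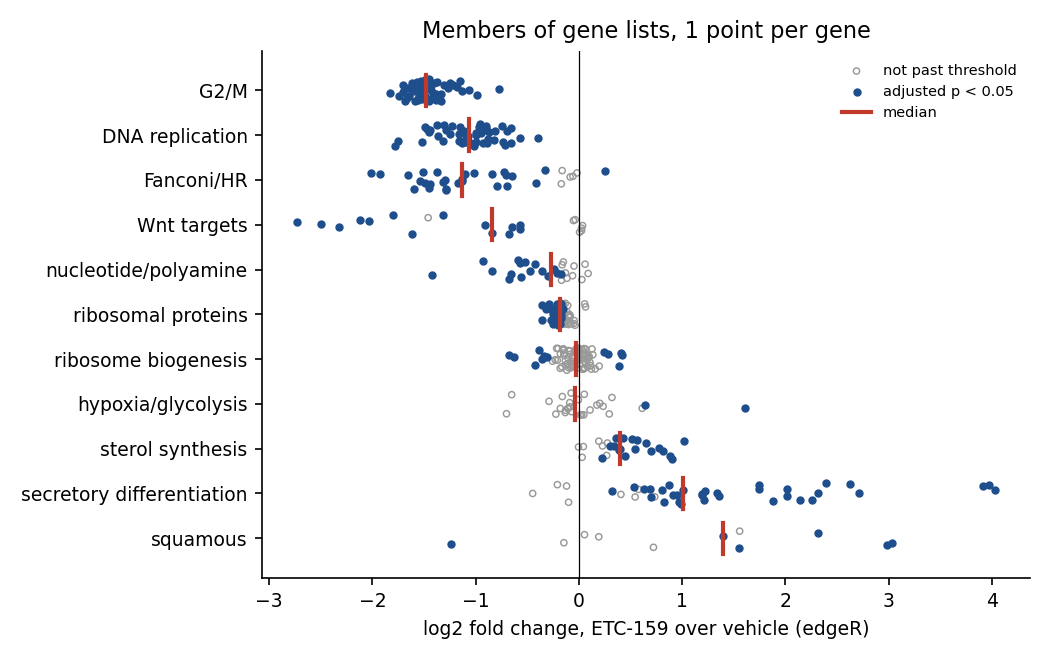
Log2 fold change, ETC-159 over vehicle, of the tested members of 11 gene lists, with 1 point per gene, filled where the edgeR adjusted p was under 0.05, and a red bar at the median. The medians run from -1.48 for G2 and mitosis to 1.40 for squamous genes, and all members of the G2/M and DNA replication lists lie below 0.

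The other lists did not pass the camera threshold. The balance of their calls differed between scalings. With library size only, the genes higher and lower were 3 and 12 for interferon-stimulated genes, 4 and 3 for apoptosis genes, and 6 and 7 for MAPK targets. They were 4 and 4 for immediate early genes, 5 and 8 for lysosomal genes and 4 and 5 for cell cycle exit. Without a filter on low counts MAPK targets (adjusted p = 0.0217), apoptosis genes (adjusted p = 0.0335) and immediate early genes (adjusted p = 0.0467) passed it. MAPK targets rose in 9 of 25 cases and fell in 5, also when adjusted over the list alone (median log2 fold change 0.24, camera adjusted p = 0.138, with a median of -0.00142 on log2(TPM + 1)), with DUSP4 at 65.8 ± 6.52 and 111 ± 13.7 CPM (SD, n = 5 each; edgeR adjusted p = 1.3e-05). IER3 was among the MAPK targets that fell, at 92.6 to 123 CPM in vehicle and 75.8 to 84.6 CPM in ETC-159 libraries. Notch genes had 2 of 11 higher and 4 lower, and 2 and 5 adjusted over the list alone (median log2 fold change -0.24, camera adjusted p = 0.744). Hypoxia and glycolysis genes had 2 of 28 higher and none lower, also when adjusted over the list alone (median log2 fold change -0.04, camera direction up, adjusted p = 0.907). They had 3 higher and 3 lower with 1 surrogate variable, 2 and 4 with library size only and 3 and 4 among replicates 1 to 3 alone. In the main fit the members that rose were HK2, with a log2 fold change of 0.64 ± 0.09, and CA9, with 1.60 ± 0.36 (SE, edgeR adjusted p = 5.4e-05 and 0.0075). Among replicates 4 and 5 alone, the log2 fold change of CA9 was 1.14, with adjusted p = 0.0783, the highest of 26 alternatives. Interferon-stimulated genes had 6 of 25 higher and 5 lower, and 8 and 5 adjusted over the list alone (median log2 fold change -0.03, camera direction up, adjusted p = 0.626), with OASL higher by 0.75 ± 0.10 and OAS3 lower by 0.48 ± 0.07 on the log2 scale (SE, edgeR adjusted p = 3.7e-05 and 0.000132).

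Lysosomal and autophagy genes had 8 of 27 higher and 6 lower, also when adjusted over the list alone (median log2 fold change 0.05, camera adjusted p = 0.374, with a median of -0.11 with library size only), with the protease gene CTSD at 749 ± 84.98 and 1252 ± 120 CPM (SD, n = 5 each; edgeR adjusted p = 1.5e-05). The list of apoptosis and death receptor genes was not limited to pro-apoptotic members and also held inhibitors of apoptosis. It had 9 of 20 higher and 1 lower, and 10 and 1 adjusted over the list alone (median log2 fold change 0.19, camera adjusted p = 0.0918, with a median of -0.06 on log2(TPM + 1)). With limma-voom the camera adjusted p of this list was 0.0261, and with fry the adjusted p was 0.00057. The member that fell was the death receptor gene FAS, from 5.31 ± 0.67 to 2.38 ± 0.76 CPM (SD, n = 5 each; edgeR adjusted p = 0.000383). Immediate early and heat shock genes, which respond to tissue handling, had 5 of 18 higher and 2 lower, also when adjusted over the list alone (median log2 fold change 0.10, camera adjusted p = 0.141, with a median of -0.05 with library size only). With fry the adjusted p of the immediate early list was 0.00619. FOS rose by 0.77 ± 0.08 on the log2 scale (SE, edgeR adjusted p = 6.8e-06). EGR1 was among those lower, at 18.9 to 26.4 CPM in vehicle and 13.1 to 21.2 CPM in ETC-159 libraries. The 13 protein-coding genes of the mitochondrial genome had none past the threshold, also when adjusted over the list alone, with a median log2 fold change of -0.31 (camera adjusted p = 0.35), which was -0.139 without vehicle replicate 3 and -0.476 without ETC-159 replicate 2. Nuclear genes of the respiratory chain had 1 of 33 higher and 5 lower, and 1 and 4 adjusted over the list alone (median log2 fold change -0.10, camera adjusted p = 0.351). On log2(TPM + 1) the camera adjusted p of that list was 0.00625.

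The 10 protein-coding genes with the largest rises under the naming rule were MUC17, TFF1, PSCA, GUCA2B, ACHE, KRT16, SPRR1B, B3GNT6, FER1L6 and REG4. MUC17 (ENSG00000169876, chromosome 7) rose by 4.03 ± 0.33 on the log2 scale and the surface antigen gene PSCA (ENSG00000167653, chromosome 8) by 3.92 ± 0.29, from 12.6 ± 2.77 to 189 ± 64.1 CPM (SD, n = 5 each; edgeR adjusted p = 2.3e-05 and 9.9e-06). GUCA2B, encoding the intestinal peptide uroguanylin, rose from 0.807 ± 0.356 to 11.3 ± 2.51 CPM, and FER1L6 from 23.2 ± 4.31 to 150 ± 27.2 CPM (SD, n = 5 each; edgeR adjusted p = 6.9e-08 and 3.7e-07). The largest falls were those of AXIN2, SP5, EDAR, H1-3, NEURL1B, NKD1, VWA5B2, ID3, H3C12 and EME1. The ectodysplasin receptor gene EDAR went from 13.5 ± 1.45 to 2.40 ± 0.91 CPM and the linker histone gene H1-3 from 36.2 ± 6.13 to 7.29 ± 2.35 CPM (SD, n = 5 each; edgeR adjusted p = 4.3e-07 and 1.9e-06).

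Because the tumours grew in mice and only a human build is listed, markers of host cells were examined. Scaled to library totals, the collagen gene COL1A1 had 8.74 to 13.25 CPM, and the leukocyte, endothelial, fat and blood genes PTPRC, PECAM1, CDH5, ADIPOQ and HBB had under 1 CPM in every library. Of 7 tested fibroblast genes 1 rose and 2 fell, also when adjusted over the list alone (median log2 fold change -0.20, camera direction up, adjusted p = 0.852), with S100A4 higher by 1.24 ± 0.09 and VIM lower by 1.27 ± 0.31 on the log2 scale (SE, edgeR adjusted p = 1.3e-07 and 0.0105). FN1 fell by 0.72 ± 0.23 (SE, edgeR adjusted p = 0.036), and its adjusted p ran from 0.0542 to 0.0788 without vehicle replicate 1, 2, 4 or 5 or ETC-159 replicate 1, 3 or 4. The leukocyte list had 4 tested genes, of which CD68 and CORO1A rose and LYZ fell, also when adjusted over the list alone. The endothelial list had 1 tested gene, ESAM, which fell by 0.61 ± 0.15 on the log2 scale (SE, edgeR adjusted p = 0.0051), also when adjusted over the list alone. No gene of the muscle, fat and blood list was tested. All host lists together took 0.384 ± 0.0898% of counts in vehicle and 0.178 ± 0.0482% in ETC-159 tumours (SD, n = 5 each; exact permutation p = 0.00794, the smallest it can give, adjusted p = 0.0222). Most of this share was LYZ, a lysozyme gene that gastrointestinal epithelium also expresses, at 3419 ± 840 and 1619 ± 468 CPM (SD, n = 5 each). Without LYZ, CD74, S100A4 and VIM the share was 0.0185 ± 0.00106% and 0.0198 ± 0.00097% (SD, n = 5 each; exact permutation p = 0.0873, adjusted p = 0.136). Before adjustment the exact permutation p was 0.00794 as a share of TPM and 0.0476 without ETC-159 replicate 5.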

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

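Each group of 5 libraries was searched, for the genes named by the rule and every composition measure, for a library whose gap to the nearest other exceeded Dixon's 95% critical value, given here as the gap over the range of the group. For genes, gap and range were taken on log2(CPM + 0.5). Of 346 groups, 19 (5.491%) held such a library, and chance alone gives about 1 in 20. No explanation was tested for any of them.

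Vehicle replicate 3 stood apart in 8 cases. It was the highest of its group for NOP56 (0.766), RRP12 (0.7122), ETV5 (0.8255) and VIM (0.7505), and the lowest for FER1L6 (0.8415), CTSD (0.7106), EFNB1 (0.7692) and FN1 (0.7769). ETC-159 replicate 2 stood apart in 6 cases. It was the highest of its group for the cell cycle genes RRM2 (0.7162), TOP2A (0.8046) and HMMR (0.8211) and for the histone gene H1-3 (0.713), and the lowest for BAK1 (0.8448) and CD68 (0.9253). TOP2A was at 90.3 CPM in that tumour and at 63.7 to 68.2 CPM in the other ETC-159 tumours, all below the vehicle tumours. Vehicle replicate 2 was highest for FOS (0.7556) and lowest for EGR1 (0.7447). SP5 was lowest in vehicle replicate 5 (0.8281), at 6.71 CPM against 14.1 to 16.3 CPM in the other vehicle tumours. ENO2 was highest in ETC-159 replicate 4 (0.7542) and SPRR1B highest in ETC-159 replicate 5 (0.8091).

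Chance as the source of the number of changed genes was tested by splitting the 10 libraries in other ways into groups of 5. Of the 126 splits 100 were drawn, with the real one included by design, and only the real one gave 5293 or more genes. Every other split drawn mixed the groups on each side, so a difference between the groups added to the spread within its sides. The result is thus 1 in 100 at best and does not exclude chance. Nor can it tell ETC-159 from time or any other difference between the groups. The highest other split gave 568 genes and the median of the others was 0. In that split vehicle replicate 5 changed places with ETC-159 replicate 2.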

How the results depend on the processing

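The fits on part of the replicate numbers and on thinned libraries were chosen after seeing the data, the former because replicates 4 and 5 stood apart on the second principal component and in PORCN. The number of changed genes stayed between 4549 and 5642 when any 1 library was left out, and was 5316 with DESeq2 size factors (5241 shared with the main 5293), 5321 by the DESeq2 Wald test (4953 shared), 5347 by limma-voom (5191 shared), 5023 without a filter on low counts, 5274 with a stricter one, 4892 among protein-coding genes, 6390 with 1 surrogate variable, 5287 without the host lists, 4871 after thinning to equal depth, 3891 among replicates 1 to 3 and 3768 among replicates 4 and 5. Library size only gave 1417 higher and 4927 lower genes, log2(TPM + 1) 636 and 4760, and log2(TPM + 0.1) 639 and 4748. Library size only shifts all genes by nearly the same amount by construction, and so moved the medians of all 28 lists down, and it gave 74 ribosomal protein genes lower, 21 nuclear genes of the respiratory chain lower, and 6 genes of Wnt machinery higher and 11 lower. In the TPM fits single lists moved either way and the test and the pseudocount changed too, and the cause was not tested. With library size only and on log2(TPM + 1) the medians were 0.24 and 0.14 for sterol synthesis, 0.09 and 0.04 for axon guidance and 0.05 and -0.05 for the ATF4 and unfolded protein responses. These lists kept a camera adjusted p under 0.05 in both settings. Without a filter on low counts the medians were -1.44 for Wnt targets and 0.485 for squamous genes. An adjusted p under 0.01 left 3412 genes, 1624 of them lower, and glmTreat against a fold of 1.5 left 709, of which 269 were higher and 440 lower. With an estimated correlation the medians were the same, but camera called 2 lists, Wnt targets and G2/M, of the 12 called with the preset one. The calls lost were those of ribosomal proteins (-0.19), DNA replication (-1.06), homologous recombination (-1.13), secretory differentiation (1.01), nucleotide and polyamine synthesis (-0.27), squamous genes (1.40), TGF-beta and BMP targets (-0.16), the ATF4 and unfolded protein responses (0.21), sterol synthesis (0.40) and axon guidance (0.25). Among replicates 4 and 5 alone the ribosomal protein median was -0.095 (adjusted p = 0.212, with alternatives from 5.6e-09 to 0.709), and the cause was not tested. With any 1 library left out, medians ran from -0.869 to -0.699 for Wnt targets, -1.57 to -1.42 for G2/M, -1.16 to -0.992 for DNA replication, -1.25 to -1.05 for homologous recombination, 0.983 to 1.09 for secretory differentiation, -0.207 to -0.168 for ribosomal proteins and -0.0584 to 0.0227 for ribosome biogenesis. Other medians that moved by over 1.5 times ran from 0.072 to 0.146 for cell cycle exit, -0.194 to 0.0761 for hypoxia and glycolysis, 0.0718 to 0.15 for immediate early genes, -0.0679 to 0.0199 for interferon-stimulated genes, 0.0249 to 0.0732 for lysosomal genes, 0.149 to 0.306 for MAPK targets, -0.284 to -0.0645 for Notch genes, -0.263 to -0.126 for fibroblast genes, -0.047 to 0.00672 for translation factors and -0.0448 to 0.0127 for Wnt machinery. RRP12 turned to -0.00874 and -0.0102 and NOTCH2 to -0.00973 and -0.0108 on the TPM scales with pseudocounts of 1 and 0.1, and the difference in the fibroblast share turned to 0.000648 percentage points as a share of TPM. The cause of these reversals was not tested. A value past the threshold in neither fit counted as kept even if its sign turned, the direction of a list was that of camera, and the side of a share of counts was taken from its p before adjustment. Of the other comparisons of single named genes with an alternative, 3994 kept their side of the threshold, 109 lost and 41 gained it. For gene lists 755 kept it, 14 lost and 13 gained it. With the replicate number of the titles as a block, 5439 genes changed, 5044 of them shared, 3 hypoxia and glycolysis genes were higher and 3 lower, and 4 named genes gained the threshold, PORCN (adjusted p = 0.04955), CDKN1A (adjusted p = 0.01235), ENO2 (adjusted p = 0.00285) and CA12 (adjusted p = 0.02383). Deviations from the group mean correlated at 0.126, -0.0937, 0.143, 0.209 and 0.353 between libraries of the same number, and not every sample correlated best with its own number, so the numbers are not treated as pairs. The file names carry other numbers, which would pair the libraries differently and were not used, so the block and these correlations hold for the title numbers only. In simulated data 74.6% of 1.5-fold changes were recovered, 9 of 25 (36%) among genes below the median abundance and 41 of 42 (97.62%) above it (Fisher's exact p = 2.58e-08), a split chosen after seeing the data, and depth itself was varied only by thinning.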

Other observations

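The 6 gene families in this part and the tests of shared growth genes and histone classes were chosen after the results were seen. The camera p-values of these families were adjusted over the 6 families alone, apart from the 28 lists. Their adjusted p-values are therefore not comparable with those of the lists. With an estimated correlation the p before adjustment was 0.0126 for the brush border and 0.00986 for the secretory differentiation list, whose adjusted p was 0.092. Genes of the intestinal brush border rose in 26 of 27 cases, also when adjusted over the list alone, with a median log2 fold change of 0.71 (camera adjusted p = 3.2e-17, and adjusted p = 0.0301 with an estimated correlation). VIL1, encoding villin, went from 548 ± 29.5 to 889 ± 73.4 CPM, and the cadherin-related CDHR2 of microvillus tips from 66.1 ± 8.44 to 143 ± 13.1 CPM (SD, n = 5 each; edgeR adjusted p = 2.8e-06 and 4.3e-07). A family of glycosyltransferases and carbohydrate sulfotransferases was picked by gene symbol and is not limited to mucin-type glycosylation. Its members rose in 23 of 57 cases and fell in 9, and 24 and 9 did so adjusted over the list alone (median log2 fold change 0.10, camera adjusted p = 0.00211, and adjusted p = 0.12 with an estimated correlation). Drug and aldehyde metabolising enzymes rose in 18 of 65 cases and fell in 15, and 18 and 16 did so adjusted over the list alone (median log2 fold change 0.09, camera adjusted p = 0.0404, and adjusted p = 0.298 with an estimated correlation). Long non-coding RNAs fell in 179 and rose in 76 of 1175 cases, and in 139 and 67 adjusted over the list alone (median log2 fold change -0.15, camera adjusted p = 0.0988). The medians of glycosyltransferases and sulfotransferases and of metabolising enzymes were negative with library size only (-0.05 and -0.06) and on both TPM scales. There the median of all genes was lower still (-0.17, -0.20 and -0.25), so this does not bear on these families. The other families kept their sign under the 5 other scalings tried.

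Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, fell in 47 of 49 cases and rose in none, also when adjusted over the list alone, with a median log2 fold change of -1.52 (camera adjusted p = 3.9e-48, and adjusted p = 0.0301 with an estimated correlation). The 10 tested histone genes outside that family had a median of -0.34, with 6 lower and none higher, also when adjusted over the list alone (camera adjusted p = 0.000389, and adjusted p = 0.0276 with an estimated correlation). Their quartiles were -0.70 and -0.13, against -1.74 and -1.19 in the replication-dependent family. This argues against an equal loss of all histone transcripts, while a smaller general loss stays open. H2AX (-1.24) and H2AZ1 (-0.76) were among those lower, and H3-3B had a log2 fold change of 0.12 (edgeR adjusted p = 0.215). The share of cells in S phase was not measured, so no biological explanation was tested. Reads shared between near-identical histone genes were not tested as a source.

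The small fall of ribosomal protein genes was weighed against technical sources. Summing each gene with its processed pseudogenes left a median of -0.187, and 0 of 10000 random lists matched on gene length and abundance (0%) had a median as low, although matched genes are not correlated as ribosomal proteins are. The median of the list was below 0 under every scaling tried, from -0.41 on log2(TPM + 0.1) to -0.18 with DESeq2 size factors. Relative to the median of all genes it ran from -0.214 to -0.158. A library factor shifts all genes alike, so the choice of factor cannot make a fall relative to the typical gene. For the same reason these values do not decide whether the genes fell on an absolute scale, which stays open. The median of ribosome biogenesis was -0.0265, with 5 of 79 genes higher and 7 lower. With any 1 library left out it ran from -0.0584 to 0.0227, against -0.207 to -0.168 for ribosomal proteins. These values argue against a fall of equal size in ribosome biogenesis genes as a list. A smaller fall shared by growth genes stays open. Members of that list went both ways with an SD of 0.189, which is the spread of single genes and not the uncertainty of the median. What also stays open is a response to ETC-159, as a hypothesis that no test here decides. The call itself was lost among replicates 4 and 5 alone, where the median was -0.095. It was also lost with an estimated correlation (adjusted p = 0.709), where the median was unchanged.

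PORCN differed within both groups, by 2.24-fold among vehicle and 3.63-fold among ETC-159 libraries, with the highest values in replicates 4 and 5 of each. Comparisons of these 4 libraries with the other 6 had been run and were withdrawn, because the libraries had been picked by their PORCN values. No explanation of the difference is offered, and the labels do not say whether replicates 4 and 5 shared a batch.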
